A study of Mus musculus with 12 samples.

How the data were processed

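The series holds 12 libraries of mouse E14 embryonic stem cells grown in 2 dimensions. E14 is a standard mouse embryonic stem cell line. The labels put 3 libraries in each of 4 groups: untreated control cells, cells given the amino acid L-proline for 72 h, cells given budesonide for 72 h, and cells given proline and budesonide together for 72 h. Budesonide is a synthetic glucocorticoid. The labels give no doses. Replicate numbers 1 to 3 come from the sample titles. Nothing in the labels says that the replicates were separate cultures, so the p-values of single genes measure the spread between these libraries, which may be technical.

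Per the labels' protocols, total RNA was extracted on columns and libraries were made with a 3′ end kit for polyadenylated RNA (QuantSeq 3′ mRNA). Such a kit makes about 1 fragment per transcript near its 3′ end, so a count follows the number of transcripts and should depend little on transcript length. The submitters' processing notes name bcl2fastq, cutadapt 2.5, STAR 2.7.5c, featureCounts 2.0, DESeq2 and the genome build GRCm39, with no role or order. The annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Counts of genes with near-identical copies, such as Pou5f1 with its pseudogenes, Ftl1 and the histone gene H4c9, are therefore uncertain.

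The authors deposited a table of whole-number counts for 53819 gene symbols in the 12 libraries, and 25076 symbols had at least 1 count. A second deposited table holds a normalised signal, each count divided by a size factor of its library, for 19196 symbols. These were the symbols with at least 11 counts summed over the libraries, and 100% of the values equalled the count over the size factor within 0.01. The size factors ran from 0.729 to 2.16 and were those DESeq2 gives. The tests used the counts. Totals per library ran from 5.30 to 15.9 M counts. Intervals and floors that rest on counts cover counting error only, because they pool the 3 libraries of a group and leave out the spread between them. The labels name no molecular identifiers, so copies of 1 fragment may be counted more than once and these intervals may be too narrow.

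Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 13852 genes, and libraries were scaled by TMM. The quasi-likelihood F test (glmQLFit and glmQLFTest, two-sided) was fitted to all 12 libraries with 1 coefficient per group, so that the spread rested on 8 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05 with no fold threshold. A gene is said to have risen or fallen where it was called. Log2 fold changes used edgeR's prior count of 0.125 and are given with a standard error (SE). The SE was worked back from the test, as the absolute log2 change over the square root of the F statistic. CPM values are a gene's counts scaled by the TMM-adjusted total of its library, as mean ± SD over n = 3 libraries. The median biological coefficient of variation was 0.293.

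There were 6 comparisons: proline against control, budesonide against control, both compounds against proline, both against control, both against budesonide, and the interaction. The interaction is the proline effect in the presence of budesonide minus the proline effect in its absence. A further value, the share of the proline effect kept with budesonide, is the median over genes called in proline against control of the ratio of those effects on the log2 scale, which share no library. The design, the gene lists and the rule for named genes were fixed before the data were examined.

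There were 23 gene lists: naive pluripotency, general pluripotency, formative and primed epiblast, primitive streak and mesoderm, neuroectoderm, extraembryonic and definitive endoderm, trophoblast, 2-cell-like, germline, feeder fibroblast, cell-cell adhesion and epithelial, mesenchymal transition, collagen and basement membrane, amino acid starvation response (Atf4 targets), proline metabolism and transport, glucocorticoid receptor targets, hedgehog pathway, Wnt targets, cholesterol synthesis, glycolysis and hypoxia, p53 targets, immediate early and heat shock, and mitochondrially encoded. The mitochondrial list had 9 tested genes, among them the ribosomal RNAs mt-Rnr1 and mt-Rnr2. Some genes stand in more than 1 list. Lists with at least 5 tested members were tested with edgeR's camera (two-sided, preset inter-gene correlation 0.01), which compares a list with all other genes, and p-values were adjusted over the lists within a comparison. Camera with an estimated correlation and fry (limma 3.58.1) were run beside it. For each list the members called were also counted after adjustment over the list alone.

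Named genes are the called genes with the largest rises and falls whose 3 libraries in 1 group all lay above the 3 of the other, with a higher group mean of at least 10 CPM. The rule took 8 rises and 8 falls for proline and for budesonide against control and for both compounds against proline, 4 and 4 for the other pairs of groups, and 6 and 6 for the interaction, where no separation was asked. Added to these were up to 4 members of each list with the smallest p in the comparison and 20 check genes, among them Nr3c1, Fkbp5, Tsc22d3, Pou5f1, Sox2, Nanog, Zfp42, Esrrb, Fgf5, Otx2, Dnmt3b, Cdh1, Cdh2, Vim, Asns, Trib3, Smo, Ptch1 and Gli1. Symbols of predicted genes were passed over. The check gene T (brachyury) did not pass the count filter.

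Each test was first run on simulated counts drawn from the means and library sizes of the real data, with known changes put in. Of 67 genes changed by a log2 of 2, the test recovered 61.2% in proline against control, 68.7% in budesonide against control, 62.7% in both compounds against proline, 76.1% in both against control, 62.7% in both against budesonide and 53.7% in the interaction. Of 67 genes changed by a log2 of 1 it recovered 37.3%, 38.8%, 28.4%, 35.8%, 25.4% and 19.4% in the same order. Camera called the shifted list and none of 20 random lists.

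Comparisons that share libraries share their chance values, so 20 sets of unchanged groups were simulated. They were used for the pairs of proline against control with a comparison that shares its libraries, and not for other pairs. Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 10 CPM in 3 libraries, a test against a 1.5-fold change, the replicate number as a block, only the 6 libraries compared, and each library left out in turn. Chosen after seeing the data were a fit without control 3 and budesonide 3 and a fit in which each library's trend of log2 CPM on transcript length, GC content and internal A-rich stretches was removed through offsets. Lengths and sequences for that fit came from a GENCODE annotation of build GRCm38, which matched 97.7% of the tested genes by symbol. Because this is another build than the authors', no coordinates are given.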

Results

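Messenger RNA was counted in 12 libraries of E14 mouse embryonic stem cells grown in 2 dimensions: 3 of untreated cells, 3 after 72 h with L-proline, 3 after 72 h with the synthetic glucocorticoid budesonide, and 3 after 72 h with both. L-proline is known to drive embryonic stem cells from a naive state towards a primed, mesenchymal-like state. The layout allows the proline effect to be measured without and with budesonide. The control libraries held 6.12, 5.30 and 6.73 M counts (M for mega), the proline libraries 15.9, 6.78 and 7.27 M, the budesonide libraries 8.48, 6.03 and 7.54 M, and the libraries of both compounds 6.58, 6.96 and 7.52 M. Genes are named by the symbols of the deposited table.

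Libraries of a group resembled each other with correlations of log2 CPM of 0.887 to 0.956 across genes, which are not independent replicates. No libraries were repeats of each other, since the chi-square per degree of freedom between replicates was 5.81 or higher. Control 3 and budesonide 3 stood apart from the rest, with no count for 6.57% and 8.43% of the tested genes, against 1.39% to 5.77% in the other libraries. The ribosomal RNA Rn18s took 2.55% ± 0.303 of the counts in control (SD, n = 3), 2.87% ± 0.519 with proline, 4.36% ± 2.22 with budesonide and 4.51% ± 1.39 with both, and it reached 6.70% in budesonide 3. Mitochondrially encoded genes took 7.58% ± 0.243 in control, 5.62% ± 0.156 with proline, 7.72% ± 0.280 with budesonide and 7.95% ± 0.0708 with both (SD, n = 3). The proline share lay below the control share with p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 libraries allow.

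**Figure D1:**
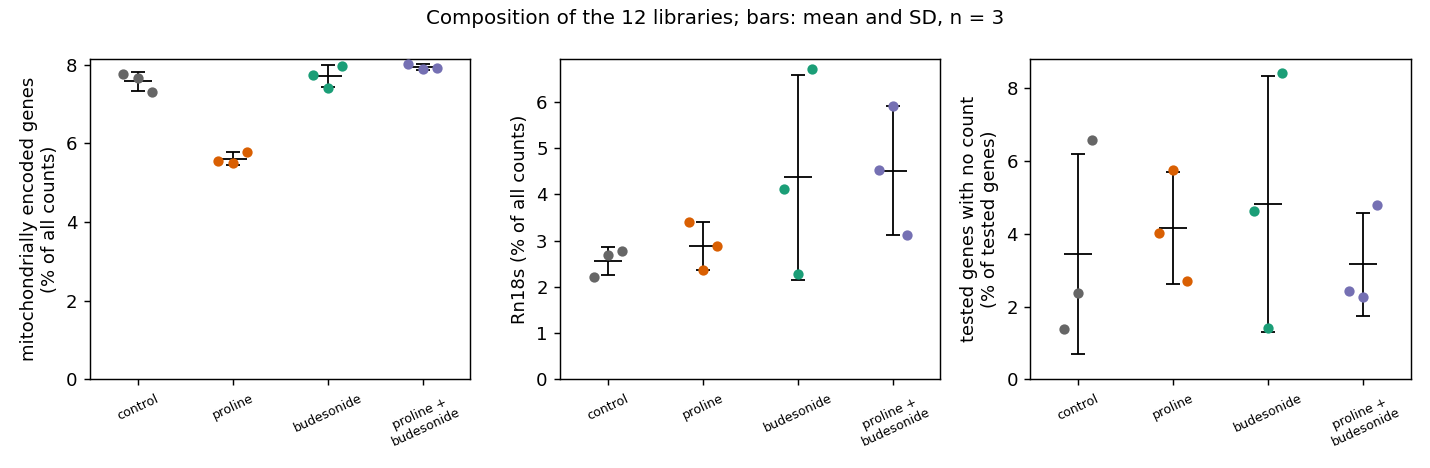
Share of all counts from mitochondrially encoded genes (left) and from Rn18s (middle), and share of tested genes with no count (right), each in percent, for the 12 libraries in 4 groups; points are libraries and bars the mean and SD of 3. The mitochondrial share was 5.62% with proline and 7.58% to 7.95% in the other groups.

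The first question was what 72 h of proline did to the cells. Transcripts of the naive pluripotency network were lower after proline, and transcripts that mark the formative and primed epiblast were higher. Of 22 naive genes, 15 fell and 7 were not called, or 17 fell when adjusted over the list alone. Their median log2 change was −1.06 (camera adjusted p = 9.25e-40, or 9.73e-06 with an estimated correlation). The naive transcription factor Tfcp2l1 went from 238 ± 10.2 to 51.5 ± 3.73 CPM (SD, n = 3), a log2 change of −2.21 ± 0.12 (SE). Esrrb, an orphan nuclear receptor of the naive network, changed by −1.67 ± 0.14 and Klf4 by −1.47 ± 0.15, while Nanog changed by −0.97 ± 0.15. Of 22 formative genes, 13 rose and 9 were not called, with a median of 1.18 (adjusted p = 3.95e-34, or 2.64e-05 with an estimated correlation). Adjusted over the list alone, 15 rose and 1 fell. Pou3f1, a POU transcription factor of the primed epiblast, went from 53 ± 9.22 to 471 ± 70.2 CPM, a log2 change of 3.15 ± 0.16. The de novo DNA methyltransferase Dnmt3b went from 382 ± 6.02 to 1212 ± 75.4 CPM, and Otx2, which drives exit from the naive state, rose by 1.22 ± 0.14 on the log2 scale. Fgf5, the growth factor of the postimplantation epiblast, had 295 counts with proline and 1 in control, a ratio of 179 (95% counting interval 31.8 to 7080).

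Genes of the amino acid starvation response, the targets of the transcription factor Atf4, were also lower with proline. Of 33, 11 fell, 1 rose and 21 were not called (adjusted p = 2.27e-05), and adjusted over the list alone 14 fell and 2 rose. Asparagine synthetase (Asns) went from 302 ± 47.6 to 134 ± 2.45 CPM, and the cysteine synthesis enzyme Cth and the cationic amino acid transporter Slc7a1 had log2 changes of −1.35 ± 0.20 and −1.41 ± 0.15. The proline and glutamine carrier Slc38a2 was the member that rose, by 0.42 ± 0.09. Of 25 cholesterol synthesis genes 4 rose (adjusted p = 7.91e-05; 6 adjusted over the list alone), among them the sterol demethylase Cyp51 at 1.06 ± 0.18. Of 25 glycolysis and hypoxia genes 8 rose and 2 fell (adjusted p = 0.00948; 0.175 with an estimated correlation and 0.0669 with transcript length and GC offsets, range over alternatives 0.00150 to 0.175), including lactate dehydrogenase Ldha at 0.60 ± 0.11 and triosephosphate isomerase Tpi1 at 0.82 ± 0.12. Adjusted over the list alone, 8 rose and 3 fell. Of the 22 collagen and basement membrane genes 5 fell and 1 rose, adjusted over the list alone as well (median −0.12, adjusted p = 0.0225; 0.0680 with an estimated correlation, range 0.00627 to 0.0680), with the laminin chain Lama1 at −1.65 ± 0.19 and nidogen (Nid1) at −1.70 ± 0.26. Of 9 mitochondrially encoded genes 6 fell (7 adjusted over the list alone; adjusted p = 2.27e-05), mt-Cytb by −0.49 ± 0.08 (−0.28 with transcript length and GC offsets), in the libraries in which these genes took the smallest share of counts. The mitochondrial list's adjusted p was 0.0627 with an estimated correlation and 0.802 with the offsets (range 9.24e-07 to 0.802).

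In all, 439 genes rose and 652 fell with proline, of 13852 tested, and 26.7% of all tested genes had libraries of the groups that did not overlap, against 10% by chance. Outside the lists, the largest rises among the named genes included the metalloproteinase Mmp25 (log2 4.42 ± 0.73, adjusted p = 0.000338), Enpp2, which makes lysophosphatidic acid (3.22 ± 0.31, adjusted p = 2.42e-07), and Zfp608 (3.04 ± 0.51, adjusted p = 0.000361). The largest falls included Lrrn2 (−3.60 ± 0.49, adjusted p = 2.91e-05), apolipoprotein D (Apod, −2.66 ± 0.54, adjusted p = 0.00229) and the microtubule protein tau (Mapt, −2.49 ± 0.24, adjusted p = 3.41e-07). Of the 1091 calls, 192 passed a test against a 1.5-fold change, 54 higher and 138 lower. The count was 725 without control 1, 674 without proline 1 and 711 without proline 3.

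The second comparison asked what budesonide alone did. Some naive genes were higher than in control. Of 22 formative genes 2 rose and 6 fell, or 4 and 8 adjusted over the list alone, and the list was not called (adjusted p = 0.0867). It was called lower without control 3 (adjusted p = 0.0129), without budesonide 3 (0.0282), without both of these (0.00422), with no low-count filter (0.0480) and with length and GC offsets (0.0328), over a range of 0.00422 to 0.240. Of 22 naive genes 5 rose and 17 were not called (adjusted p = 0.00178, median 0.19), and adjusted over the list alone 8 rose and 1 fell. Klf2 went from 449 ± 35.3 to 863 ± 94.3 CPM (SD, n = 3), and Tbx3 and the adhesion receptor Pecam1 had log2 changes of 0.78 ± 0.13 and 1.15 ± 0.23. Esrrb stood at 376 ± 56.7 and 368 ± 38.3 CPM (adjusted p = 0.939). Of 14 general pluripotency genes 3 fell or 4 adjusted over the list alone (adjusted p = 0.00474; 0.0505 with an estimated correlation, range over alternatives 0.000634 to 0.0505), led by the Nodal co-receptor Tdgf1 at −0.93 ± 0.13. Of 16 trophoblast genes 2 rose, or 5 adjusted over the list alone (adjusted p = 0.00178), the keratin Krt18 by 1.47 ± 0.32 and the homeobox gene Rhox6 by 1.77 ± 0.44. The call of Rhox6 ended without control 1 (adjusted p = 0.0610), control 2 (0.0627) or budesonide 2 (0.0655) and with limma-voom (0.0742), over a range of 0.00181 to 0.0742. Of 14 primitive streak and mesoderm genes 2 rose and 2 fell, adjusted over the list alone as well, and the list was not called (adjusted p = 0.253). Those that rose were the Lefty genes, inhibitors of Nodal signalling, Lefty1 by 1.13 ± 0.14 and Lefty2 by 1.29 ± 0.17. Those that fell were the transcription factor Sp5 (−3.59 ± 0.80; adjusted p = 0.0769 with limma-voom and 0.0706 with only the 6 libraries, range 0.000112 to 0.0769) and Bmp4 (−0.58 ± 0.17). The Bmp4 call ended without control 1 (adjusted p = 0.0774), control 2 (0.136), control 3 (0.0938), budesonide 2 (0.0991) or budesonide 3 (0.151), with no low-count filter (0.0790), with only the 6 libraries (0.0821) and with offsets (0.110), and the highest value was 0.210 without control 3 and budesonide 3 together (range 0.00888 to 0.210).

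The collagen and basement membrane list rose as well, with 6 of 22 members higher and 3 lower or 9 and 3 adjusted over the list alone (adjusted p = 0.0195; 0.0578 with an estimated correlation). The proteoglycan perlecan (Hspg2) went from 115 ± 13.4 to 292 ± 49.2 CPM (SD, n = 3) and fibronectin (Fn1) changed by 0.69 ± 0.11, while the laminin chain Lamb1 changed by −0.76 ± 0.13. Of 33 adhesion and epithelial genes 3 rose, or 5 with 1 lower when adjusted over the list alone (adjusted p = 0.0210; 0.0578 with an estimated correlation), among them Krt18. Of 15 Wnt targets 3 fell, or 4 adjusted over the list alone (adjusted p = 0.0112, or 0.0578 with an estimated correlation, range 0.000650 to 0.0578). The 3 were cyclin D1 (Ccnd1) at −1.49 ± 0.19, and Sp5 and Bmp4. The latter are also streak genes, and their calls ended under alternatives as given above. Of 20 germline genes 2 fell, or 3 adjusted over the list alone (adjusted p = 0.00513; 0.0982 with an estimated correlation, range 0.000634 to 0.0982): Mael at −1.55 ± 0.29 and Tex19.1 at −0.74 ± 0.15, both of which act in silencing transposons. The adhesion call also ended without control 1 (adjusted p = 0.0514), without budesonide 3 (0.0723) and without control 3 and budesonide 3 together (0.109; range over alternatives 0.00249 to 0.109). The collagen call ended with no low-count filter (0.0811) and with length and GC offsets (0.466; range 0.00889 to 0.466).

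Genes that glucocorticoids are known to induce did not move as a set. Of 25 tested, 2 rose and 3 fell with budesonide, or 2 and 4 adjusted over the list alone (adjusted p = 0.586). The NF-kappa-B inhibitor Nfkbia rose by 0.82 ± 0.13, while the cell cycle inhibitor Cdkn1c went from 206 ± 17 to 68.5 ± 18 CPM (SD, n = 3) and the metallothionein Mt2 changed by −0.59 ± 0.11. Fkbp5, a common glucocorticoid-induced gene, stood at 99.7 ± 5.66 and 85.8 ± 16.2 CPM (log2 −0.21 ± 0.16, adjusted p = 0.524). Tsc22d3 was near the detection limit at 0.539 ± 0.492 and 1.60 ± 1.49 CPM, and the receptor gene Nr3c1 stood at 11.1 ± 1.95 and 18.1 ± 3.32 CPM (adjusted p = 0.187).

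In all, 348 genes rose and 554 fell with budesonide, and 23.7% of all tested genes had libraries that did not overlap, against 10% by chance. Outside the lists, the largest rises included the haem-responsive repressor Bach1 (log2 2.49 ± 0.38, adjusted p = 0.000307), Camk2n1, an inhibitor of a calcium-dependent kinase (2.35 ± 0.44, adjusted p = 0.00165), and properdin (Cfp, 2.14 ± 0.46, adjusted p = 0.00609). The largest falls included Dync2i2, a chain of the ciliary dynein (−2.00 ± 0.33, adjusted p = 0.000629), and the homeobox gene En1 (−1.72 ± 0.37, adjusted p = 0.00525). The change also went with transcript length. The median log2 change was −0.236 for transcripts up to 1 kb and 0.209 for those over 8 kb, and the deviation of a library's log2 CPM from the mean of the 12 libraries correlated with length, across genes, at 0.144 to 0.217 in the budesonide libraries and −0.0921 to −0.0621 in control. The Rn18s share of the budesonide libraries, 4.36%, against 2.55% in control, had p = 0.3 in a two-sided exact permutation test. Control 3 and budesonide 3, which stood apart, both enter this comparison, and without them 575 genes were called, of which 454 were among the 902. A fit of only the 6 libraries called 493, and 24 genes passed a test against a 1.5-fold change, of which 17 were higher and 7 lower, a balance opposite to that of all calls.

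**Figure D2:**
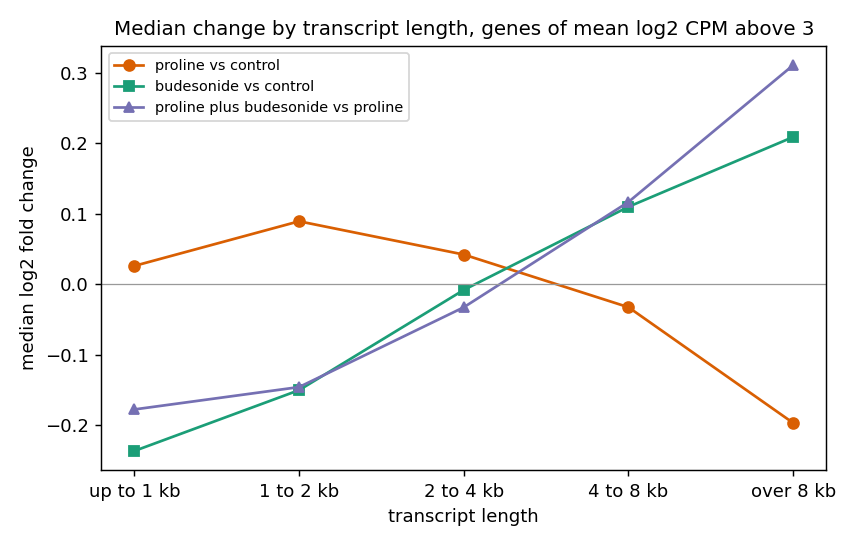
Median log2 fold change of genes in 5 classes of transcript length, for genes with a mean log2 CPM above 3, in 3 comparisons. In budesonide against control the median went from −0.236 in transcripts up to 1 kb to 0.209 over 8 kb, and in both compounds against proline from −0.177 to 0.311.

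The third comparison asked what budesonide did in cells that also received proline. Naive genes were higher and formative genes lower than with proline alone. Of 22 naive genes 15 rose and 7 were not called, adjusted over the list alone as well. Their median log2 change was 1.14 (adjusted p = 1.44e-39, or 9.92e-06 with an estimated correlation). Tbx3 went from 22.9 ± 2.27 to 155 ± 7.59 CPM (SD, n = 3), Tfcp2l1 from 51.5 ± 3.73 to 190 ± 15.5 and Esrrb from 118 ± 13.3 to 340 ± 53.4, and Klf2 and Nanog had log2 changes of 1.72 ± 0.11 and 1.33 ± 0.15. Of 22 formative genes 11 fell and 11 were not called, or 12 fell and 1 rose adjusted over the list alone. The list's adjusted p was 2.23e-16, or 0.000444 with an estimated correlation. Pou3f1 went from 471 ± 70.2 to 140 ± 14.5 CPM, the kinase gene Pim2 from 368 ± 26.3 to 79.0 ± 3.82, and Dnmt3b and Dnmt3a changed by −1.47 ± 0.11 and −1.45 ± 0.13. Otx2 changed less, by −0.80 ± 0.14.

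**Figure D3:**
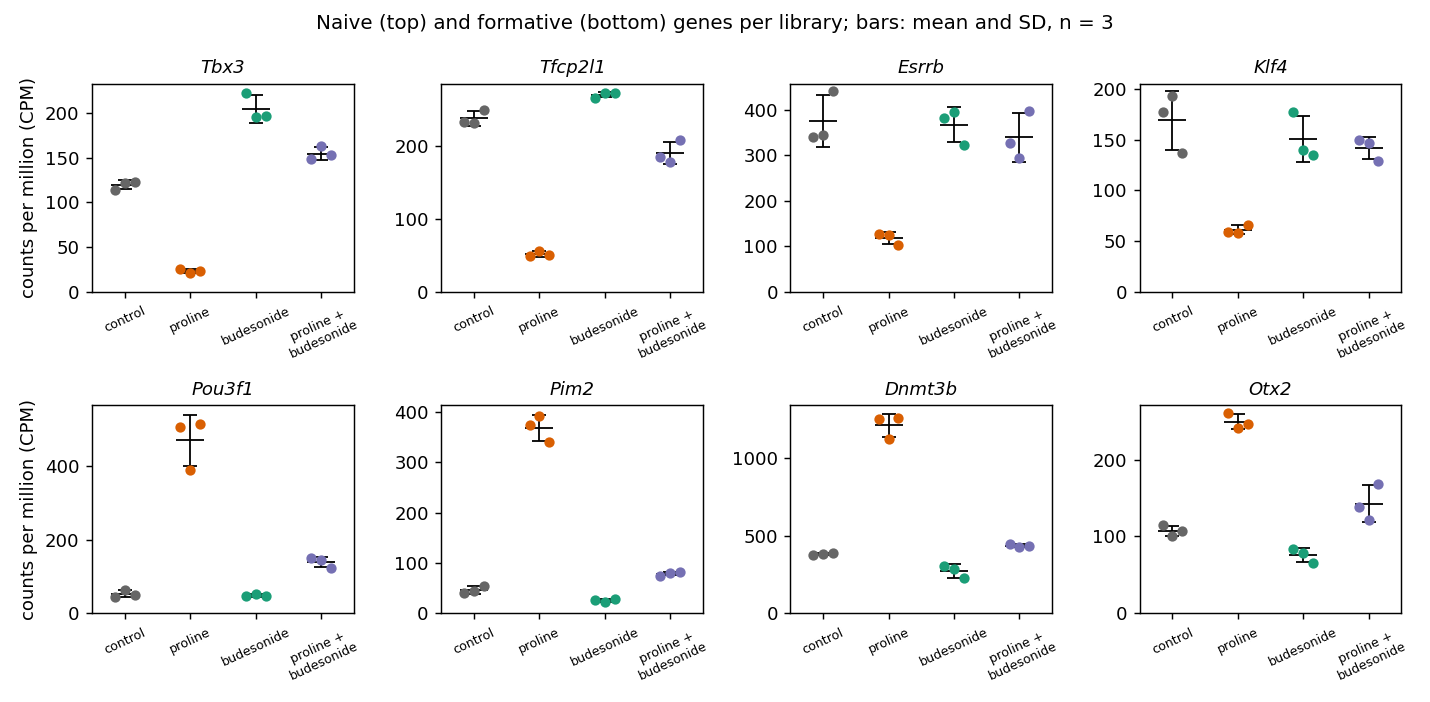
CPM of 4 naive genes (top) and 4 formative genes (bottom) in the 12 libraries; points are libraries and bars the mean and SD of 3. Tfcp2l1 stood at 51.5 CPM with proline and 190 with both compounds, and Pou3f1 at 471 and 140.

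Of the 22 collagen and basement membrane genes 8 rose and 2 fell, or 10 and 2 adjusted over the list alone (adjusted p = 2.20e-06), with log2 changes of 2.51 ± 0.26 for Nid1, 1.95 ± 0.17 for Hspg2 and 1.32 ± 0.19 for Lama1. Of 16 trophoblast genes 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (adjusted p = 0.000569). They included the keratin Krt8 at 3.56 ± 0.52, Rhox6 at 2.23 ± 0.44 and the transcription factor Tfap2c at 1.38 ± 0.21. Of 9 mitochondrially encoded genes 6 rose, adjusted over the list alone as well (adjusted p = 2.72e-06), mt-Cytb by 0.79 ± 0.08, as their share of counts went from 5.62% ± 0.156 to 7.95% ± 0.0708 (n = 3). With length and GC offsets 4 of the 9 rose, the list median went from 0.539 to 0.336 (quartiles −0.129 and 0.600), and the call of mt-Nd4 ended (adjusted p = 0.194, range over alternatives 9.46e-07 to 0.194). Of 14 general pluripotency genes 3 fell, or 3 with 1 higher adjusted over the list alone (adjusted p = 0.00455), among them Tdgf1 at −0.80 ± 0.13 and Utf1 at −0.85 ± 0.12. The germline list was lower with only Mael called, at −1.76 ± 0.29 (adjusted p = 0.0295; 0.216 with an estimated correlation, 0.0695 without proline 1 and 0.0604 with length and GC offsets, range 0.00704 to 0.216). Cdkn1c and Mt2 were lower here too, at −1.20 ± 0.17 and −1.05 ± 0.12, and Nfkbia and Klf9 higher, at 1.34 ± 0.13 and 0.81 ± 0.09.

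In all, 808 genes rose and 591 fell with budesonide in the presence of proline, and 31.9% of all tested genes had libraries that did not overlap, against 10% by chance. The largest rises included the water and glycerol channel Aqp3 (log2 4.22 ± 0.70, adjusted p = 0.000312), the fatty acid carrier Fabp3 (4.09 ± 0.64, adjusted p = 0.000142), the transcription factor Sox21 (2.88 ± 0.36, adjusted p = 9.47e-06) and the cholesterol exporter Abca1 (2.84 ± 0.37, adjusted p = 1.94e-05). The largest falls included the surface protein Thy1 (−3.29 ± 0.62, adjusted p = 0.000976), Sema6a (−2.79 ± 0.42, adjusted p = 8.86e-05), Prtg (−2.23 ± 0.41, adjusted p = 0.000769) and the fatty acid carrier Fabp5 (−2.15 ± 0.34, adjusted p = 0.000180). Of the genes called for budesonide alone, 194 rose and 233 fell here as well, where independent lists would share 20.3 and 23.6, and these comparisons share no library. Of the genes called for proline, 467 moved the opposite way here: 138 that had risen, with 18.7 for independent lists, and 329 that had fallen, with 38.0. These comparisons share the proline libraries. The fold changes correlated at −0.581 across genes, with −0.485 in simulated unchanged groups, and their covariance was −0.586 with −0.268 simulated, a difference of −0.318. Part of the excess may come from the shared libraries, which were too few to split. The count was 920 without proline 1, 836 without replicate 1 of both compounds and 870 without replicate 2, and 216 genes passed a test against a 1.5-fold change, 181 higher and 35 lower. With length and GC offsets 622 rose and 599 fell.

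The fourth comparison asked whether cells given both compounds returned to the untreated profile. The naive list did not differ as a set (adjusted p = 0.548), with 1 of 22 members called, or 4 higher and 4 lower adjusted over the list alone. Klf2 was the member called, at 0.72 ± 0.11, and Esrrb and Nanog stood at 340 ± 53.4 and 278 ± 11.2 CPM against 376 ± 56.7 and 217 ± 41 in control (SD, n = 3; adjusted p = 0.622 and 0.15). Formative genes remained higher than in control, with 6 up and 2 down of 22, or 7 and 2 adjusted over the list alone (adjusted p = 0.000308). Pou3f1 was higher by 1.40 ± 0.15, Tcf7l1 by 1.10 ± 0.18, Zic5 by 1.14 ± 0.24 and Pim2 by 0.78 ± 0.14, while Dnmt3b differed by 0.19 ± 0.11 (adjusted p = 0.358). Atf4 targets stayed below control, with 11 lower and 2 higher of 33, or 15 and 2 adjusted over the list alone (adjusted p = 5.21e-07), Asns at −0.96 ± 0.13, Cth at −1.38 ± 0.20 and the serine synthesis enzyme Psat1 at −1.21 ± 0.13. Glycolysis genes were higher, with 7 of 25 up, or 13 adjusted over the list alone (adjusted p = 1.94e-05), including the glucose transporters Slc2a1 at 0.74 ± 0.10 and Slc2a3 at 1.0 ± 0.12. Cholesterol genes were higher, with 5 of 25 up, adjusted over the list alone as well (adjusted p = 1.94e-05), with the sterol sensor Insig1 at 1.65 ± 0.35 and Cyp51 at 0.79 ± 0.18.

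Further lists were called in the same comparison. Of 16 trophoblast genes 3 rose, or 4 adjusted over the list alone (adjusted p = 0.00335), with Tfap2c at 0.95 ± 0.21, and of 20 germline genes 2 fell, or 3 (adjusted p = 0.000602), with the ribosomal protein gene Rpl10l of the testis at −0.82 ± 0.18. Of 33 adhesion genes 3 rose and 1 fell, or 5 and 2 adjusted over the list alone (adjusted p = 0.0215; 0.0778 with length and GC offsets, range 0.00247 to 0.0778). Of 22 collagen genes 5 rose and 2 fell, or 7 and 3 adjusted over the list alone (adjusted p = 0.0141; 0.265 with offsets, range 0.00552 to 0.265). The primitive streak and mesoderm list was higher, with 2 of 14 up and 1 down, adjusted over the list alone as well (adjusted p = 0.0182; 0.0506 with an estimated correlation, 0.0794 without control 2 and 0.147 with no low-count filter, range 0.00745 to 0.147). The members that rose were Lefty1 at 1.94 ± 0.14 and Lefty2 at 1.84 ± 0.17, and Bmp4, which helps to induce mesoderm, was lower at −0.74 ± 0.17, a call that ended without replicate 1 of both compounds (adjusted p = 0.0546, range 0.0219 to 0.0546 with 1 library left out). Of 19 p53 targets 3 fell, or 3 with 1 higher adjusted over the list alone (adjusted p = 0.0408), among them Ccng1 at −0.65 ± 0.11 and Perp at −1.44 ± 0.28. That call ended with an estimated correlation (adjusted p = 0.0948) and without control 1 (0.101), control 2 (0.0501), or replicate 2 (0.0965) or 3 (0.0544) of both compounds, over a range of 0.0119 to 0.101.

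In all, 462 genes rose and 531 fell, and 28.4% of all tested genes had libraries that did not overlap, against 10% by chance. The Rn18s share was 4.51% with both compounds against 2.55% in control, with p = 0.1 in a two-sided exact permutation test, the smallest that 3 against 3 libraries allow. The largest differences included the transcription factor Bhlhe40 (log2 3.49 ± 0.54, adjusted p = 0.000238) and Camk2n1 (2.77 ± 0.44, adjusted p = 0.000311), which were higher, and Apod (−2.95 ± 0.55, adjusted p = 0.00144), the stress response gene Nupr1 (−2.53 ± 0.49, adjusted p = 0.00200) and the protease inhibitor Spink1 (−2.07 ± 0.19, adjusted p = 4.69e-07), which were lower. With proline alone, 121 of these rises and 162 of these falls were called as well, where independent lists would share 14.6 and 25. The fold changes correlated at 0.457 across genes with 0.513 in simulated unchanged groups, and their covariance was 0.422 with 0.289 simulated, a difference of 0.133. Part of the overlap may come from the shared control libraries, too few to split. The count was 537 without replicate 1 of both compounds and 535 without replicate 2, and 83 genes passed a test against a 1.5-fold change, 48 higher and 35 lower.

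The fifth comparison gave the proline effect in cells that also received budesonide. The formative list was higher, and the Atf4 and naive lists were lower. Of 22 formative genes 5 rose and 1 fell, or 10 and 1 adjusted over the list alone (adjusted p = 3.69e-13, or 0.00208 with an estimated correlation). Log2 changes were 1.62 ± 0.15 for Pim2, 1.52 ± 0.15 for Pou3f1, 0.91 ± 0.14 for Otx2 and 0.68 ± 0.11 for Dnmt3b. Of 33 Atf4 targets 4 fell, or 13 with 2 higher adjusted over the list alone (adjusted p = 3.93e-07), including Cth at −1.24 ± 0.20, Slc7a1 at −0.92 ± 0.15 and Asns at −0.82 ± 0.12. The naive list had a median of −0.19 (adjusted p = 0.0010), with 6 of 22 members lower adjusted over the list alone. Over all genes Tfcp2l1 was the member called, at −0.51 ± 0.12, and its adjusted p lay above 0.05 without budesonide 1, 2 or 3 or replicate 1 or 2 of both compounds, over a range of 0.0452 to 0.137, and was 0.104 with length and GC offsets (range over alternatives 0.000383 to 0.137). The cholesterol list was higher (adjusted p = 0.00173), although edgeR called none of its 25 members over all genes, and 3 rose adjusted over the list alone. At an unadjusted p below 0.05, 7 were higher, and over all genes limma-voom called 1 and DESeq2 3. Cyp51 stood at 0.65 ± 0.18 (adjusted p = 0.0636 over all genes). Of 25 glycolysis genes 3 rose, or 7 with 1 lower adjusted over the list alone (adjusted p = 0.000206; 0.0657 with an estimated correlation, range 1.49e-05 to 0.0657), with Slc2a1 at 0.57 ± 0.10.

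In all, 121 genes rose and 82 fell, and 19.4% of all tested genes had libraries that did not overlap, against 10% by chance. The largest changes included Enpp2 (log2 2.79 ± 0.33, adjusted p = 3.63e-05) and Ccno, a cyclin-like gene (2.12 ± 0.33, adjusted p = 0.00153). Of the 439 genes that rose with proline alone 66 rose here, and of the 652 that fell 59 fell, where independent lists would share 3.83 and 3.86, and these comparisons share no library. The count was 135 without budesonide 1, 92 without budesonide 3, and 80, 102 and 82 without replicates 1, 2 and 3 of both compounds. It was 354 with no low-count filter, 450 with DESeq2, 120 in a fit of only the 6 libraries, 128 with length and GC offsets, and 7 in a test against a 1.5-fold change. Without budesonide 3, 8 lists were called in place of 5.

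The sixth comparison, the interaction, tested whether the proline effect differed with budesonide. It did for 65 genes, 57 with a positive and 8 with a negative interaction. Of 22 naive genes 7 had a positive interaction, or 14 adjusted over the list alone. Their median log2 interaction was 0.88 (adjusted p = 1.10e-29, or 3.06e-05 with an estimated correlation). Tbx3 had an interaction of 1.97 ± 0.19 (adjusted p = 3.82e-06), Tfcp2l1 of 1.71 ± 0.17, Zfp42 of 1.56 ± 0.23 and Esrrb of 1.55 ± 0.19. Of 22 formative genes 4 had a negative interaction, or 8 adjusted over the list alone (adjusted p = 6.97e-12, or 0.00156 with an estimated correlation). The 4 were Pou3f1 at −1.63 ± 0.21, Pim2 at −1.37 ± 0.20, Dnmt3a at −1.0 ± 0.18 and Dnmt3b at −0.99 ± 0.16. Of 9 mitochondrially encoded genes 3 had a positive interaction, or 9 adjusted over the list alone (median 0.499, adjusted p = 7.03e-11, or 0.0117 with an estimated correlation). With transcript length and GC offsets that median was 0.235 and the calls of the 3 ended. Of 22 collagen genes 2 did, adjusted over the list alone as well (adjusted p = 0.0129; 0.0570 with an estimated correlation and 0.0858 without budesonide 2, range 0.00172 to 0.0858). The Atf4 targets Cth and Slc7a1 had interactions of 0.11 ± 0.28 and 0.48 ± 0.21 (adjusted p = 0.960 and 0.510).

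Over the 1091 genes called with proline, the median ratio of the proline effect with budesonide to that without it was 0.385 (quartiles 0.186 and 0.624), and 969 kept their sign. The ratio was 0.475 for genes that rose and 0.340 for genes that fell. By list, the called members had a median ratio of 0.219 for 15 naive genes, 0.407 for 13 formative genes, 0.690 for 12 Atf4 targets, 0.580 for 10 glycolysis genes and 0.310 for 6 collagen genes. It was 0.302 for 4 cholesterol genes (quartiles −0.0638 and 0.691), of which 2 kept their sign. For 6 mitochondrially encoded genes it was −0.157, and 0 of these kept their sign. All of the 1091 genes were chosen for their proline effect, which lowers the ratio. With genes chosen on 2 replicates and the ratio taken from the other, it was 0.405, 0.426 and 0.466, and the ratio of the median effects was 0.397, 0.448 and 0.593. These rest on 328, 414 and 1026 genes. The last takes its effects from replicates numbered 3, among them control 3 and budesonide 3, which stood apart. The interaction called 134 genes with no low-count filter and 157 with DESeq2, and 10 against a 1.5-fold change. Without replicate 2 of both compounds 7 lists were called in place of 4.

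**Figure D4:**
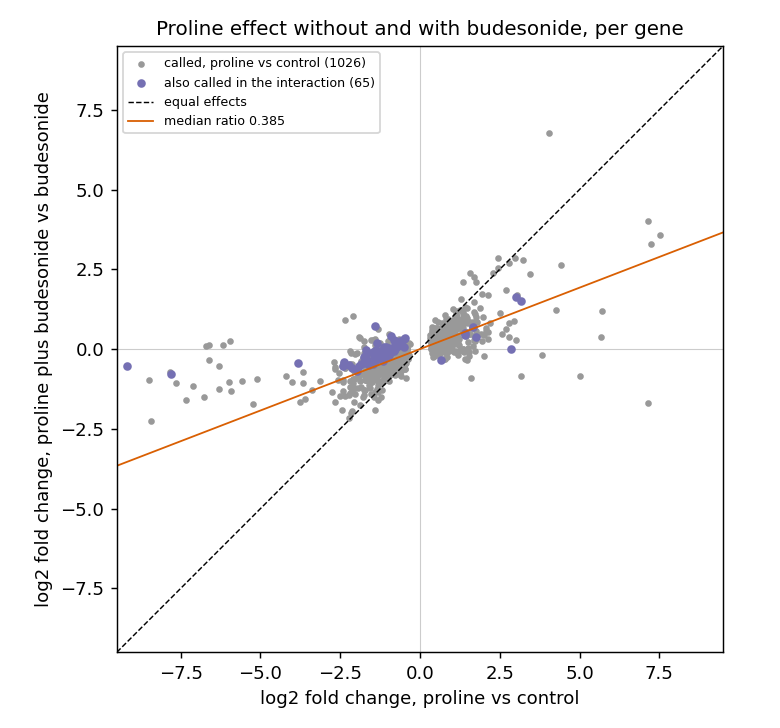
Log2 fold change of proline against control (horizontal) and of both compounds against budesonide (vertical) for the 1091 genes called in the former; each point is a gene, purple points are the 65 also called in the interaction, the dashed line marks equal effects and the orange line the median ratio of 0.385. Of the 1091 genes, 969 kept their sign.

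Other lists were not called by camera in any of the 6 comparisons. The lowest camera adjusted p was 0.0546 for 8 genes of the 2-cell-like state, 0.0883 for 12 neuroectoderm genes, 0.110 for 16 genes of proline metabolism and transport, 0.120 for 14 endoderm genes, 0.128 for 11 feeder fibroblast genes, 0.253 for 16 immediate early and heat shock genes, 0.292 for 24 genes of the mesenchymal transition, 0.459 for 11 genes of the hedgehog pathway and 0.571 for 25 glucocorticoid receptor targets. Fry, which does not set a list against the other genes, gave an adjusted p below 0.05 for some lists. Its lowest was 0.00579 for proline metabolism (higher with proline), and 0.0247 for 2-cell-like and 0.0383 for immediate early genes (lower with budesonide). In both compounds against proline it was 0.0105 for mesenchymal transition, 0.0232 for endoderm and 0.0349 for hedgehog (higher), and 0.0349 for feeder fibroblast genes (lower). The 2-cell-like list was called lower in budesonide against control without control 2 (adjusted p = 0.0441), control 3 (0.0201), budesonide 2 (0.0357) or budesonide 3 (0.00506), and without control 3 and budesonide 3 together (0.00422, range 0.00422 to 0.294). E-cadherin (Cdh1) stood at 670 ± 69.9 CPM in control, 761 ± 161 with proline, 644 ± 121 with budesonide and 783 ± 84.2 with both (SD, n = 3), with adjusted p of 0.429 or more in all 6 comparisons. The pluripotency factor Sox2 stood at 526 ± 46.5, 458 ± 20.4, 515 ± 64.8 and 570 ± 14.3 CPM in the same order. Pou5f1 was counted at 29.8 ± 3.15, 30.3 ± 4.96, 27.1 ± 4.63 and 26.9 ± 8.36 CPM, a low level that is uncertain because its pseudogenes can share its reads. N-cadherin (Cdh2) was low, at 3.38 ± 1.58, 9.44 ± 3.57, 2.37 ± 0.248 and 4.02 ± 1.08 CPM. Vimentin (Vim) stood at 191 ± 30.2, 218 ± 8.75, 212 ± 18.6 and 298 ± 15.2 CPM, and was higher with both compounds than in control (log2 0.64 ± 0.13, adjusted p = 0.00225). The hedgehog receptor Ptch1 stood at 74.1 ± 8.05, 74.4 ± 12.6, 77.8 ± 21.7 and 89.9 ± 13.2 CPM, and Smo and Gli1 were not called in any comparison. The streak marker T had 20, 5, 0 and 13 counts in the 4 groups, and 18 of the 20 came from control 3. It did not pass the filter on low counts.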

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

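The fits without control 3 and budesonide 3 and with length and GC offsets, as tests of the naive and mitochondrial patterns, and the left-out test of proline 1 for the mitochondrial genes, were chosen after the result was seen. Each result here stood out because the proline effect differed with budesonide, by the interaction term of edgeR's quasi-likelihood test, which called 65 genes. In 100 regroupings of the 12 libraries, the real one included, 5 called at least 65 genes. Regrouping all 12 libraries also carries the effects of proline and of budesonide into the contrast. This test can therefore neither exclude chance nor show it. The 4 others called 116, 132, 294 and 303. Counts of this size point to a structure of the samples. Each of the 4 kept 5 of the 6 libraries with budesonide, or with proline, on one side, and the 76 other regroupings called at most 61 genes. Of the 23 regroupings with such a side, however, 19 called 55 genes or fewer. Such a side alone thus did not give a high count, and what else entered stays open. For the other comparisons, 3 against 3 libraries make 10 splits, too few for a share under 0.05, and 1 split, the real one, reached the real count each time. The real count and the highest other were 1091 and 1 for proline against control, 902 and 0 for budesonide against control, 1399 and 0 for both compounds against proline, 993 and 0 for both against control, and 203 and 1 for both against budesonide.

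Among naive genes, the interaction on the log2 scale was 1.97 for Tbx3, 1.71 for Tfcp2l1, 1.56 for Zfp42, 1.55 for Esrrb and 1.01 for Nanog. Among formative genes it was −1.63 for Pou3f1, −1.37 for Pim2, −1.0 for Dnmt3a and −0.99 for Dnmt3b. Of the genes outside these lists, it was 2.14 for Calcoco2, 1.89 for Ahnak2, 1.51 for Ncam1, 1.25 for Bmp4, 0.99 for S100a6, 0.88 for Apoe, 0.80 for Slc2a3, 0.72 for Hspb1, −1.02 for Car2, −1.36 for Irf1 and −2.86 for Cnksr3. It was 1.66 for Nid1 and 1.30 for Lama1, both of the basement membrane, and 0.81 for mt-Nd2, 0.79 for mt-Nd4 and 0.56 for mt-Cytb. List medians were 0.882 for naive, −0.408 for formative, 0.315 for collagen and basement membrane and 0.499 for mitochondrially encoded genes (0.235 with length and GC offsets).

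Of the 25 named genes called in the interaction, 14 kept the call with every library left out. The highest adjusted p with 1 library left out was 0.0521 for Bmp4 (without control 2), 0.0603 for Lama1 (without budesonide 1 or replicate 3 of both compounds), 0.0700 for Cnksr3 (without proline 3 or replicate 3 of both), 0.0714 for Slc2a3 (without proline 1, budesonide 1 or replicates 1 or 3 of both), 0.0730 for Nanog (without control 1, proline 1, proline 3, budesonide 2 or replicate 1 of both) and 0.0738 for mt-Cytb (without control 1, control 2, proline 1, proline 3 or replicate 3 of both). It was 0.106 for Nid1 over 7 libraries that ended the call, 0.170 for Car2 over 9 and 0.173 for Hspb1 over 9, and 11 libraries ended the calls of Ahnak2 and S100a6. Calls also ended with limma-voom (Ahnak2, Car2 and Cnksr3), with RLE size factors (Hspb1), without control 3 and budesonide 3 together (Ahnak2, Car2, Hspb1, S100a6 and Slc2a3) and with length and GC offsets (Hspb1 and S100a6). With length and GC offsets the adjusted p was 0.107 for mt-Nd2 (range over alternatives 1.77e-06 to 0.107), 0.314 for mt-Nd4 (3.48e-07 to 0.314) and 0.310 for mt-Cytb (0.000703 to 0.310).

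The naive list's median interaction of 0.882 (0.760 to 0.948 with 1 library left out) was tested against 3 technical explanations. Without control 3 and budesonide 3, which stood apart, it was 0.969 (list adjusted p = 4.19e-33), with length and GC offsets 0.815 (3.77e-30), and with proline 1 thinned to the median depth of the other libraries 0.904 (7.23e-30). The first 2 of these values argue against those libraries and against length and GC as the whole cause. Thinning keeps each gene's expected share of its library, so it could hardly move the median and does not decide on depth. With 1 library left out, proline 1 among them, the median was 0.760 or higher. That argues against the depth of proline 1 as the whole cause. A biological explanation, that budesonide may hold back the loss of naive transcripts with proline, stays open as a hypothesis from the same data.

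The mitochondrially encoded genes, lower with proline alone by a median of −0.425 (−0.503 to −0.392 with 1 library left out), gave a less settled result. Without proline 1, the deepest library, the median was −0.471, which argues against its depth, and 76 nuclear-encoded genes of the respiratory chain had a median of −0.0676 (−0.0884 to −0.0227), which argues against a fall of all respiratory chain transcripts. Nuclear genes matched on length and GC had a median of −0.0349 (quartiles −0.531 and 0.278), and of 0.173 with length and GC offsets. With these offsets, however, the median of the 9 genes went from −0.425 (quartiles −0.500 and −0.327) to −0.0320 (−0.107 and 0.00156). A bias of sequence therefore cannot be told apart from a change in these genes, because the matched genes and the offsets point to different answers. The 2 checks also differ, since the offsets removed the trend on A-rich stretches too, on which the nuclear genes were not matched. Nor were these genes matched on expression. A biological effect of proline on mitochondrial transcripts may exist and stays open.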

How the results depend on the processing

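The fits without control 3 and budesonide 3, the length and GC offsets and the left-out libraries of the kept share were chosen after the data were seen. Totals of named genes, and their ranges over alternatives, leave out the filter of 10 CPM and the test against a 1.5-fold change. Those of lists also leave out DESeq2, limma-voom and the fits of only the 6 libraries compared. Of the called results of named genes, 4375 kept their direction and call and 579 lost the call. Of the called list results 510 kept it and 31 lost it. None of these turned direction. Of results not called, 174 of genes and 39 of lists were called under an alternative, where each alternative counts as a separate result of the same gene or list. The lists were formative and 2-cell-like in budesonide against control; Wnt and mitochondrial, neuroectoderm and streak in both against budesonide; general pluripotency in both against control; adhesion in both against proline; Wnt, 2-cell-like and proline metabolism in the interaction; and mitochondrial in budesonide and in both against control. The cause of a changed count was not tested unless stated.

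Against a 1.5-fold change, a stricter test by construction, 192 genes were called for proline against control, 24 for budesonide against control, 216 for both compounds against proline, 83 for both against control, 7 for both against budesonide and 10 for the interaction. Both against budesonide gave 354 with no low-count filter, 450 with DESeq2 and 128 with length and GC offsets, and the interaction gave 134 with no filter and 157 with DESeq2. With only the 6 libraries compared, budesonide against control gave 493 and both against budesonide 120. Proline against control gave 1056, both against control 992 and both against proline 1913. These fits all have fewer degrees of freedom, and each also takes its spread and its set of tested genes from the 6 libraries alone. These changes came together, so which of them lowered the counts that fell cannot be told. Without control 3 and budesonide 3, budesonide against control gave 575, of which 454 were among the 902. With an estimated correlation 4 of 7 lists were called for proline and 2 of 7 for budesonide against control.

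With 1 library left out, counts ran from 674 to 887 for proline, 620 to 809 for budesonide, 836 to 1095 for both against proline, 535 to 789 for both against control, 80 to 171 for both against budesonide and 44 to 89 for the interaction, with fewer samples by construction. Lists called ran from 7 to 7, 6 to 9, 6 to 7, 8 to 10, 5 to 8 and 3 to 7 in the same order. The kept share of the proline effect ran from 0.362 to 0.402, and was 0.426 and 0.466 in held-out replicates 2 and 3 (0.448 and 0.593 as a ratio of medians). With proline 1 thinned to 6.78 M counts, proline against control gave 1059, both against proline 1380 and the interaction 65.

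The replicate numbers do not pair the libraries: deviations from the group mean correlated at −0.0767 to 0.0529 over the 18 pairs of equal number in different groups. With the replicate number as a block, counts were 927, 768, 1227, 869, 128 and 46 in the same order, and the kept share 0.382. The block ended 37 calls of named genes. Among them were the calls of Tfcp2l1 in both against budesonide and of Bmp4 in budesonide against control. Those in the interaction were Nid1, Car2, Hspb1, Ahnak2, S100a6 and mt-Cytb. In simulated counts of the same depth 37.3% of genes changed by a log2 of 1 were recovered for proline against control, which limits what the counts can show.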

Other observations

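The length and GC test and the fit without control 3 and budesonide 3 were chosen after the data were seen, and the ribosomal protein genes after their values were seen. Genes that code for ribosomal proteins, which are short and abundant, were lower with budesonide alone. Of 79 such genes 50 fell and 77 lay below 0, with a median log2 change of −0.477 (−0.502 to −0.450 with 1 library left out). In both compounds against proline the median was −0.215 with 13 lower, where the 237 coding genes matched on length, GC and expression had −0.191 with 65 lower and 18 higher, and with length and GC offsets it was −0.0910 with 4 lower. In both compounds against budesonide it was 0.331 with 9 higher, where matched genes had 0.143 with 16 higher and 1 lower, and with offsets it was 0.219 with 2 higher.

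The explanations weighed were length and GC, reads moved to pseudogenes, and the libraries that stood apart. Matched coding genes, 237 in number, had a median of −0.222 with 64 lower and 6 higher, and with length and GC offsets the ribosomal protein genes had a median of −0.291 with 20 lower. The trend may thus account for part of the fall. What remained argues against it as the whole cause only as far as the matching holds, and how close the matches were was not measured. Without control 3 and budesonide 3 the median of the genes was −0.475 with 42 lower, which argues against those libraries as the cause. Reads moved to pseudogenes would have raised these, and the 92 ribosomal protein pseudogenes had a median of −0.234 (−0.284 to −0.123 with 1 library left out; −0.0336 with offsets). Their quartiles were −0.542 and 0.217, and 59 of the 92 lay below 0, so members went both ways and this explanation stays open. A lower level of ribosomal protein transcripts with budesonide stays open as well, as a hypothesis from the same data.

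The trend with transcript length differed between comparisons. The correlation of log2 change with length across genes, which are not independent, was 0.248 for budesonide against control, 0.207 for both compounds against proline and −0.0973 for proline against control. With GC content it was −0.00667, −0.0726 and 0.164 in the same order. The deviation of a library's log2 CPM from the mean of the 12 libraries correlated with length at −0.201 to −0.138 with proline and 0.0622 to 0.111 with both compounds.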
